A study of Homo sapiens with 6 samples.

How the data were processed

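RNA was sequenced from THP-1 cells, a human monocytic leukaemia line, that had been turned into macrophage-like cells with the phorbol ester PMA (50 ng/ml, 48 h). The cells were then transfected for 48 h with 200 nM of a control siRNA or of an siRNA against the circular RNA hsa_circ_0004287, and given 200 ng/ml lipopolysaccharide (LPS, a bacterial cell wall component that activates TLR4) for 3 h, per the labels' protocols. There were 3 libraries per group. The labels number them 1 to 3 in each group and do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

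Poly-A RNA was read as paired ends, per the labels' protocols. Reads were handled with CASAVA, cutadapt and HISAT2 on genome build GRCh38, per the submitters' processing notes. Their versions, the counting tool, its use of strand and the annotation release are not given in the sources used here. The deposited table gives a whole-number read count per gene and library, not normalised, and an FPKM value beside it. The FPKM values were scaled by the authors to each library's total in the same table, as checked from the counts and gene lengths, so they add no information on depth and were not used in any test. The table used here lists 19976 genes by Ensembl identifier, symbol and coordinates, of which 19889 are typed as protein-coding in GENCODE 29. A total of 19914 identifiers matched that release. Because strand and counter are not known, reads of overlapping or antisense genes and of near-identical paralogs (ribosomal protein genes with pseudogenes, and neighbouring family members) may have been split or shared, and values of such genes are uncertain.

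A circular RNA has no poly-A tail, and the gene-level table holds no row for one. The level of hsa_circ_0004287, and with it the efficiency of the knockdown, was not analysed here. MALAT1, named before the data were examined as the host gene, was not analysed here either, because the table used has 0 rows for it. The same holds for the other members of a list of nuclear long noncoding RNAs.

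The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, two-sided, with TMM scaling, filterByExpr (minimum count 10) and the group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are circ siRNA minus control siRNA, with standard errors taken from the F statistic and 95% intervals from its degrees of freedom. CPM values are counts relative to TMM-scaled library sizes, as mean ± SD over 3 libraries. For the gene lists, log2 CPM (prior count 2) was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 36 lists with at least 5 tested members, out of 42 lists written before the data were examined. A call made with the preset correlation in the fit of all 6 libraries is given with the p at the correlation estimated from the data. With an estimated correlation, camera also takes its degrees of freedom from the few libraries, so p can rise where the estimate is near 0.01. For the fits with offsets, with the replicate block or with libraries left out, the number of lists called at an estimated correlation is given.

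Genes were named by a rule set before the data were examined. It took MALAT1, IGF2BP3, S100A8, S100A9, TNF, IL1B and IL6 always. It took up to 12 called genes per direction by fold change, with non-overlapping groups and at least 5 CPM in the higher group, or else the 3 genes with the smallest p in that direction, given as not past the threshold. It also took up to 4 tested members of each list with the smallest p. Genes outside the rule appear only among the other observations, where this is said.

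Alternatives listed before the data were examined were DESeq2 size factors, library totals alone, a replicate block, leaving out each library, the Wald test of DESeq2 1.42.0, limma-voom, other filters and thresholds, and, for lists, an estimated correlation and fry. Alternatives for tables without counts did not apply. Added after the data were seen were offsets for each library's gene length and GC trend (natural splines with 4 degrees of freedom, fitted without the group labels), these offsets with the replicate block, a fit without control library 1 and circ library 3, and the estimated correlation in the fits with offsets, with the block or with libraries left out. The 3' UTR word scores were computed in Python 3.11.15 with numpy 2.4.6.

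Total counts ran from 14793902 to 16736972 per library, and 3 counts correspond to 0.179 to 0.203 CPM of the deposited totals. No pair of libraries within a group agreed within sampling noise, with a chi-square per gene of at least 5.98. In counts simulated from the real means, library totals and dispersions over 12469 genes, with 200 genes changed, the main test recovered 5.97% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 92.4% of those changed 4-fold, with 7 of 113 calls false. When each library's length and GC trend was added to the simulation, recovery of 2-fold changes was 43.3%, and 61.2% with the offsets. The trend added was of the form that the offsets fit, and the dispersions were estimated without offsets. That recovery is therefore no measure of the gain in the real data. With 2 lists shifted by 0.3 on the log2 scale, both were recovered and 0 other lists were called, in counts simulated without correlation between genes.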

Results

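The effect of silencing the circular RNA hsa_circ_0004287 on gene expression was measured in LPS-stimulated macrophages derived from THP-1 cells, by RNA sequencing of 3 libraries with control siRNA and 3 with siRNA against the circular RNA (circ siRNA). Control libraries held 16588112, 15978370 and 15874084 counts, and circ libraries 16601139, 16736972 and 14793902. Of 19976 genes listed, 3520 had no count in any library and 12469 were tested. The circular RNA itself and its host gene MALAT1 were not analysed here, so the libraries' labels could not be checked against the target.

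ROR2 was lower after circ siRNA. This gene, at chromosome 9, 91563091 to 91950228 (GRCh38, minus strand), encodes a receptor tyrosine kinase for WNT5A. Its level was 9.49 ± 1.14 CPM with control siRNA and 1.94 ± 0.20 CPM with circ siRNA (SD, n = 3 each), and all 3 circ libraries lay below all 3 control libraries. The log2 fold change was -2.29 (SE 0.19, 95% interval -2.73 to -1.85; edgeR quasi-likelihood test, adjusted p = 0.0236). No other gene passed the threshold. In edgeR, 0 genes were higher and 1 was lower, against 60 higher and 23 lower with DESeq2 and 0 with limma-voom. An unadjusted p under 0.05 was found for 470 genes with a higher and 334 with a lower value. By chance, 623 in all are expected if genes are independent. Other splits of the same 6 libraries into 3 and 3 gave from 58 to 4018 such genes. Among them, 1294 and 4018 were above the real 804. Both of these splits put control library 1 with circ library 3, which the first principal component sets apart (below). Such splits are no plain measure of chance, and the splits are few. Whether the real count exceeds chance was therefore not settled. Groups did not overlap for 1560 genes (12.5%, against 10% by chance). The ROR2 call ended when any one of the 6 libraries was left out, with edgeR adjusted p between 0.0703 and 0.205, while its log2 fold change stayed between -2.37 and -2.18. The call also ended with the replicate block and with library totals alone.

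**Figure D1:**
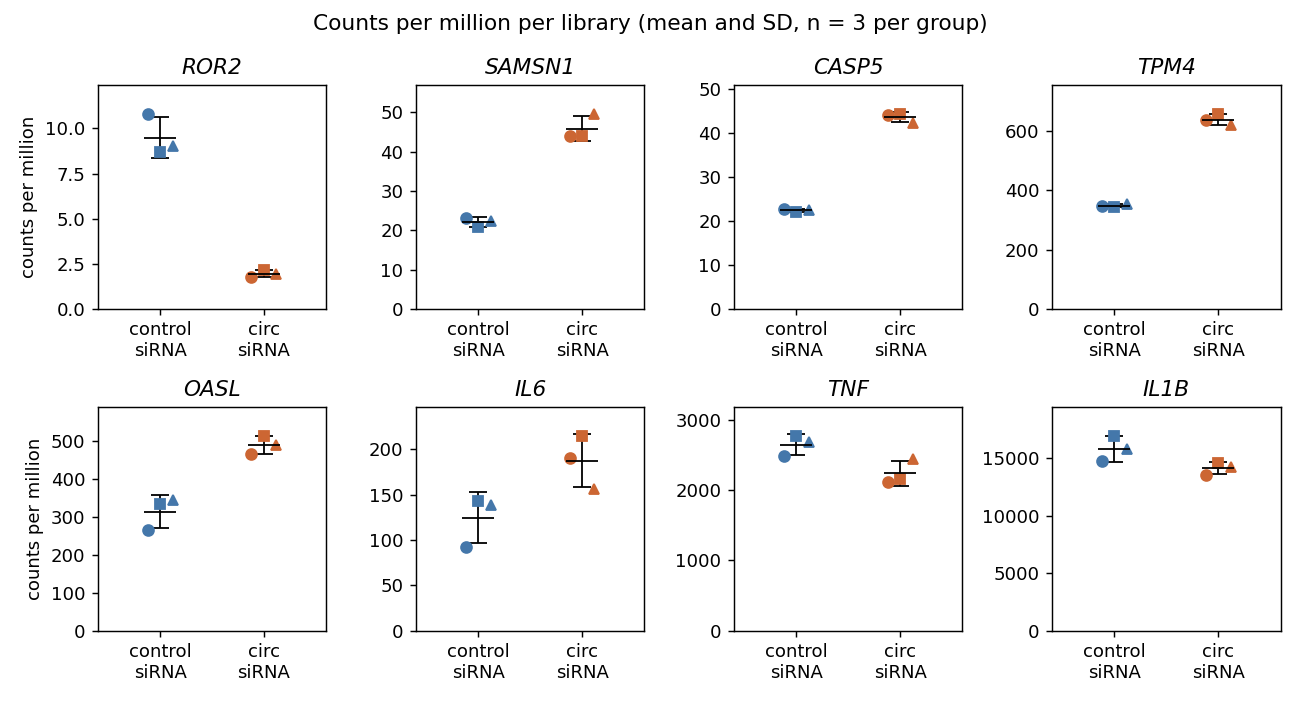
CPM (TMM-scaled) of 8 genes in each library (vertical axes start at 0), with control siRNA on the left and circ siRNA on the right of each panel; circles, squares and triangles are libraries 1, 2 and 3, and bars are the mean and SD (n = 3). ROR2 lay between 8.68 and 10.8 CPM with control siRNA and between 1.75 and 2.15 CPM with circ siRNA.

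The 3 genes with a higher value and the smallest p did not pass the threshold in the edgeR fit without offsets (adjusted p = 0.0728 each). SAMSN1, an adaptor protein of haematopoietic cells, had 22.1 ± 1.25 CPM with control siRNA and 45.8 ± 3.22 CPM with circ siRNA (log2 fold change 1.05, SE 0.12). CASP5, an inflammatory caspase that senses intracellular LPS, had 22.4 ± 0.41 and 43.6 ± 1.10 CPM (log2 fold change 0.96, SE 0.11). TPM4, a tropomyosin of the actin cytoskeleton, had 348.5 ± 5.04 and 638 ± 18.04 CPM (log2 fold change 0.87, SE 0.11). With DESeq2 these 3 genes passed the threshold, with adjusted p = 3.93e-09, 7.19e-09 and 3.93e-11. In edgeR with length and GC offsets SAMSN1 and CASP5 passed it (adjusted p = 0.0176 and 0.0374) and TPM4 did not (0.135).

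TNF, IL1B and IL6, LPS-induced cytokines named in advance, did not pass the threshold. The groups did not overlap for any of them, with TNF and IL1B lower and IL6 higher in all circ libraries, as was so for 12.5% of tested genes. IL1B was the most abundant of them, with 15835 ± 1115 CPM with control siRNA and 14141 ± 527 CPM with circ siRNA, and a log2 fold change of -0.16 (95% interval -0.47 to 0.14). TNF had 2649 ± 146 and 2242 ± 176 CPM, with a log2 fold change of -0.24 (95% interval -0.53 to 0.05). IL6 had 125 ± 28.0 and 188 ± 29.2 CPM, with a log2 fold change of 0.59 (95% interval 0.14 to 1.04, edgeR adjusted p = 0.602). With length and GC offsets the log2 fold changes of IL6, TNF and IL1B were 0.66, -0.14 and -0.14. IL6 did not pass the threshold there either (edgeR adjusted p = 0.150). Over the 24 tested members of the cytokine list, 1 was higher and 1 lower when adjusted over the list alone, and 0 when adjusted over all genes in edgeR. The list as a whole was not called by camera (adjusted p = 0.493). Its members with the smallest p were IL10, an anti-inflammatory cytokine, with a log2 fold change of 0.84, and CSF1, the macrophage growth factor, with -0.63. DESeq2 called both over all genes (adjusted p = 0.00193 and 0.00319). Of the alarmins S100A8 and S100A9, the first had 1.56 ± 0.31 and 2.04 ± 1.34 CPM and the second 9.15 ± 3.77 and 13.7 ± 4.51 CPM, with overlapping groups. With length and GC offsets S100A9 had a log2 fold change of 0.75 and did not pass the threshold (edgeR adjusted p = 0.236). IGF2BP3, an RNA-binding reader of m6A, had 0.46 ± 0.30 and 0.81 ± 0.31 CPM.

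Interferon-stimulated genes were higher as a list after circ siRNA (39 tested, mean log2 fold change 0.18; camera adjusted p = 0.000265 with the preset correlation, adjusted p = 0.490 with an estimated correlation). A total of 31 members had positive and 8 negative values, 0 members passed the gene-level threshold over all genes in edgeR, and 0 did so adjusted over the list alone. The mean of the list was above the 6-library mean by 0.10, 0.09 and 0.08 in the circ libraries, and the control libraries lay at -0.06, -0.14 and -0.06. OASL, an antiviral protein related to the oligoadenylate synthetases, had 314 ± 43.1 CPM with control siRNA and 490 ± 23.7 CPM with circ siRNA. IFIT3 had 892 ± 44.0 and 1220 ± 201 CPM. Their log2 fold changes were 0.64 and 0.45, and DESeq2 called OASL (adjusted p = 0.0163) and not IFIT3 (0.309).

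M1 macrophage markers, genes linked to pro-inflammatory activation, were higher as a list (20 tested, mean log2 fold change 0.38; camera adjusted p = 9.96e-06, adjusted p = 0.490 with an estimated correlation). Positive values were found for 19 members and a negative value for 1, and 0 passed in edgeR adjusted over all genes or over the list alone. PTGS2, the inducible cyclooxygenase, had 1019 ± 219 and 1677 ± 454 CPM, and IDO1, a tryptophan-degrading enzyme, had 27.0 ± 5.95 and 47.2 ± 7.62 CPM; DESeq2 called IDO1 (adjusted p = 0.0487). The largest part of the list's difference lay in circ library 3, at 0.53 above the 6-library mean, against 0.03 and 0.00 in circ libraries 1 and 2. Without circ library 3 the list mean was 0.21 (camera adjusted p = 0.0038, adjusted p = 0.329 with an estimated correlation), and without control library 1 and circ library 3 it was 0.18 and not called (camera adjusted p = 0.0889). M2 markers, genes linked to tissue repair, were not called in the fit of all 6 libraries (17 tested, camera adjusted p = 0.493).

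Immediate early genes, transcription factor genes induced within minutes to hours of a stimulus, were higher as a list (21 tested, mean log2 fold change 0.25; camera adjusted p = 0.00915, adjusted p = 0.490 with an estimated correlation). Positive values were found for 14 members and negative values for 7. Adjusted over the list alone, 6 members were higher and 1 lower, and adjusted over all genes 0 were in edgeR. FOSB, FOS and the nuclear receptor gene NR4A1 had log2 fold changes of 1.06, 0.43 and 1.06, and DESeq2 called FOSB (adjusted p = 0.00257). Genes of the inflammasome and pyroptosis, the machinery of caspase-driven lytic death, were also higher as a list (16 tested, mean log2 fold change 0.19; camera adjusted p = 0.0203, adjusted p = 0.490 with an estimated correlation), with CASP5 as the 1 member past the threshold adjusted over the list alone. MEFV (pyrin), CASP4 and CASP1 had log2 fold changes of 0.77, 0.35 and 0.50, and the inflammasome list held 11 positive and 5 negative values. Without control library 1 neither list was called (camera adjusted p = 0.131 for both), with list means of 0.24 and 0.17, and the inflammasome list was not called without circ library 1 (mean 0.21, adjusted p = 0.0603) or circ library 2 (mean 0.16, adjusted p = 0.134). With the replicate block and length and GC offsets together, the inflammasome list was not called either (mean 0.198, camera adjusted p = 0.0526). Whichever single library was left out, the means stayed between 0.19 and 0.30 for immediate early genes and between 0.16 and 0.27 for the inflammasome list. Without both control library 1 and circ library 3, they were 0.19 (camera adjusted p = 0.183) and 0.24 (0.0125), with adjusted p = 0.736 for both with an estimated correlation.

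Cytosolic ribosomal protein genes were lower as a list after circ siRNA (70 tested, mean log2 fold change -0.25; camera adjusted p = 7.52e-06, adjusted p = 0.820 with an estimated correlation of 0.90). All 70 had negative values and 0 passed the gene-level threshold, also adjusted over the list alone. RPS24 had 1012 ± 300 and 785 ± 72.1 CPM. The share of counts from these genes was 3.35%, 5.99% and 5.05% in control libraries 1 to 3 and 3.88%, 4.53% and 3.83% in the circ libraries, so the groups overlapped. Nuclear genes of oxidative phosphorylation were lower as a list as well (50 tested, mean log2 fold change -0.21; camera adjusted p = 0.00036, adjusted p = 0.820 with an estimated correlation of 0.65), with 45 negative and 5 positive values and 0 members past the threshold, also adjusted over the list alone. Without control library 2 the list means were -0.04 and -0.06 and neither was called (camera adjusted p = 0.432 and 0.284); without circ library 3 the oxidative phosphorylation list was not called (mean -0.11, adjusted p = 0.0872). Without control library 1 the means were larger in size, at -0.53 (camera adjusted p = 1.73e-21) and -0.42 (2.28e-10), and without both control library 1 and circ library 3 they were -0.44 (1.54e-15) and -0.31 (5.89e-08). With an estimated correlation neither list was called in these fits (adjusted p = 0.828 for both without control library 1, and 0.736 without both libraries).

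**Figure D2:**
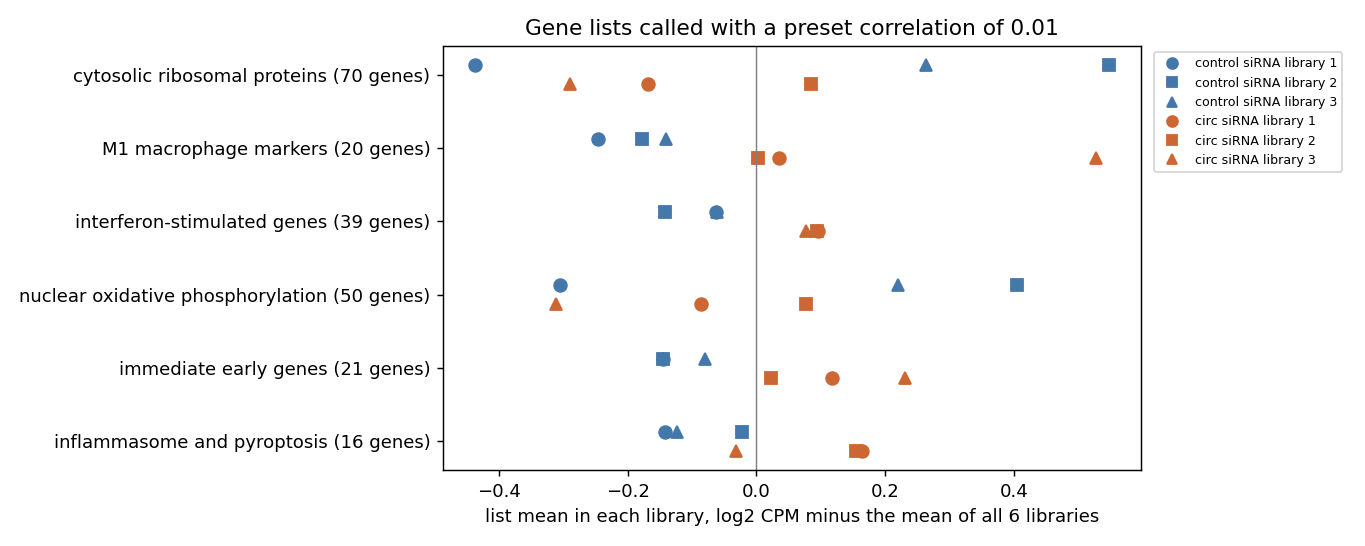
Mean of each called gene list in each library (horizontal axis, log2 CPM minus the mean of all 6 libraries), with control siRNA in blue and circ siRNA in orange, and circles, squares and triangles for libraries 1, 2 and 3. Interferon-stimulated genes lay between 0.08 and 0.10 in the circ libraries and between -0.14 and -0.06 in the control libraries, while ribosomal protein genes ranged from -0.44 to 0.55 within the control libraries.

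Of the 36 lists tested, 4 were called higher and 2 lower with the preset correlation, and 0 with an estimated correlation or with fry. The estimates for the 4 higher lists were 0.022 (interferon-stimulated), 0.28 (M1), 0.029 (immediate early) and 0.012 (inflammasome). Lists of chemokines, NF-kB targets, the TLR4 and p38 pathway, cholesterol synthesis, lysosome, p53 targets, heat shock proteins, and MHC class I and class II presentation were among those not called in this fit. Of these, MHC class II presentation was called higher with length and GC offsets (camera adjusted p = 0.0412, adjusted p = 0.550 with an estimated correlation), with the replicate block, and without control library 2, control library 3 or circ library 3. NF-kB targets were called higher with the offsets (camera adjusted p = 0.0412, adjusted p = 0.550 with an estimated correlation). The TLR4 and p38 pathway was called higher without circ library 3 (camera adjusted p = 0.0261, adjusted p = 0.329 with an estimated correlation) and without control library 1 and circ library 3 (0.0435 and 0.736), and the lysosome list without circ library 3 (adjusted p = 0.498 with an estimated correlation). With an estimated correlation, 0 lists were called in any fit with these offsets, with the replicate block or with libraries left out (lowest adjusted p = 0.238, without circ library 3). The block and the left-out libraries further reduce the few degrees of freedom, so a call was hard to reach. The 0 therefore counts neither for nor against the calls. Markers of other cell types were low. Summed over all members in the table, tested or not, and relative to the deposited library totals without TMM, epithelial markers gave 10.8 to 13.0 CPM with control siRNA and 13.0 to 16.0 CPM with circ siRNA, fibroblast markers 30.7 to 41.6 and 29.8 to 33.9 CPM, T and NK cell markers 4.04 to 7.51 and 4.66 to 5.74 CPM, and neutrophil markers 35.0 to 37.6 and 39.9 to 53.6 CPM. B cell markers gave 26.0 to 29.1 and 37.3 to 47.3 CPM, of which CD22 had (on the TMM scale) 22.7 ± 0.76 and 36.2 ± 2.44 CPM (log2 fold change 0.67; edgeR adjusted p = 0.265, DESeq2 adjusted p = 0.00257).

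The largest differences between libraries did not follow the groups. The first principal component held 53.4% of the variance and set control library 1 (-23.2) and circ library 3 (-38.4) apart from control libraries 2 and 3 (30.4 and 21.3) and circ libraries 1 and 2 (-1.51 and 11.5). The second component, with 16.9%, had circ libraries 1 to 3 at 18.5, 18.6 and -2.38 and control libraries 1 to 3 at -13.2, -13.6 and -7.92. All circ libraries thus lay above all control libraries on it. Across genes, which are not independent replicates, the deviation of control library 1 and circ library 3 from the 6-library mean rose with gene length (Spearman's rho 0.47 and 0.39), while rho was -0.44 and -0.40 in control libraries 2 and 3. The ribosomal protein and oxidative phosphorylation lists moved along the first component, with means of -0.44 and -0.31 in control library 1.

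**Figure D3:**
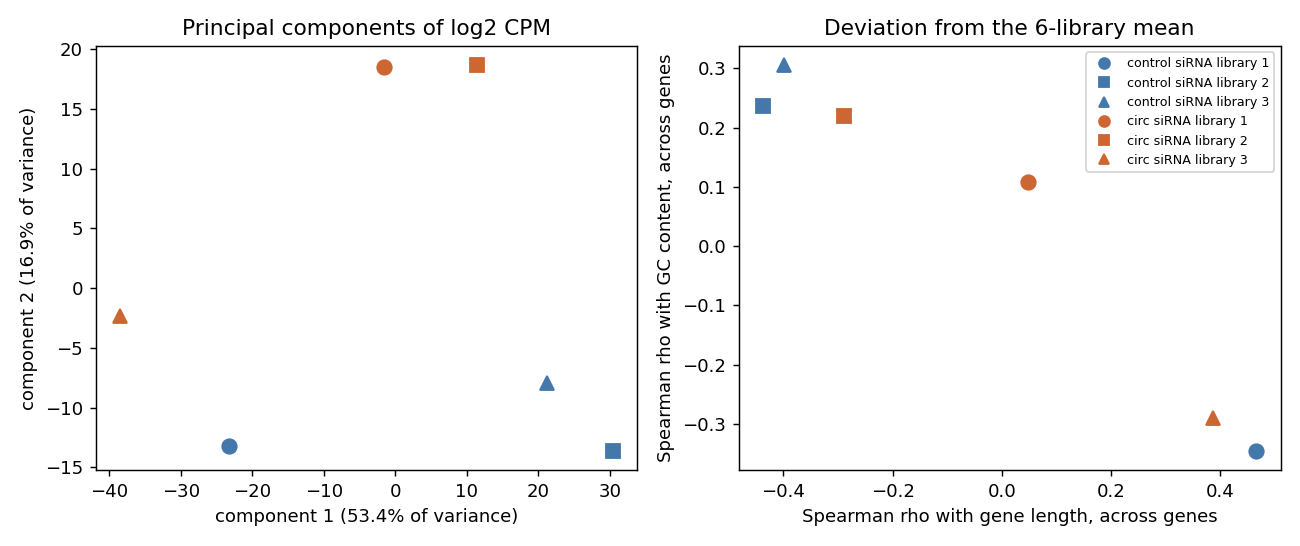
Left, the 6 libraries on the first and second principal components of log2 CPM; right, Spearman's rho across genes between each library's deviation from the 6-library mean and gene length (horizontal) or GC content (vertical), with control siRNA in blue, circ siRNA in orange and circles, squares and triangles for libraries 1, 2 and 3. Control library 1 and circ library 3 lie together in the right panel, at 0.47 and 0.39 for length and -0.35 and -0.29 for GC content.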

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

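The fits with length and GC offsets and without control library 1 and circ library 3, and the estimated correlation in these, block and leave-out fits, were chosen after the data were seen. The cause of the changes below was not tested unless it is given. Genes called higher numbered 0 in edgeR, 60 with DESeq2, 6 with length and GC offsets and 919 without control library 1 and circ library 3; genes called lower numbered 1, 23, 6 and 926. That last fit has 2 libraries per group and drops those that add most spread, so its counts are no measure of a larger effect. Genes lower numbered 0 with library totals alone, with limma-voom and at an adjusted p under 0.01, 2 without the filter, and 0 when each library was left out in turn, where genes higher also numbered 0. The replicate numbers gave no clear pairing of the samples. The correlations of same-numbered libraries' deviations were -0.17, 0.46 and -0.37, and not every library correlated best with its own number. Control library 1 and circ library 3 correlated at 0.53, and what they share may hide a pairing, so this check could not exclude one. With the replicate block 0 genes were lower and 0 higher, and with the replicate block and length and GC offsets 2 were lower. Gene lists called higher numbered 4 and lower 2; with the replicate block 5 were higher, among them MHC class II presentation, and 3 lower, among them cell cycle G1/S and replication. Both counts were 0 with an estimated correlation, alone or with the replicate block, the length and GC offsets, both of these, or libraries left out, and 0 with fry. With so few degrees of freedom, the 0 counts at an estimated correlation were likely whatever the data. With the preset correlation, 5 lists were lower without control library 1 and circ library 3, and with each library left out 2 to 9 were higher and 0 to 4 lower. S100A8 changed sign without circ library 2, its log2 fold change running from -0.071 to 0.84 as each library was left out. Of 926 gene values under alternatives, 832 kept their direction and side of the threshold, 84 passed it anew and 9 no longer did, these being ROR2. Of 240 list means, 154 kept both, 82 lost the call and 4 gained it. Genes other than ROR2, and the cytokine, NF-kB, TLR4 and p38, and M2 lists, had no call to lose. The kept values include theirs, so these tallies do not measure how stable the calls were. TMM, DESeq2 size factors and library totals shifted the median of all genes by at most 0.0245 on the log2 scale. At the low counts of IGF2BP3 the 95% interval of the log2 fold change ran from -0.45 to 1.97.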

Other observations

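Tests chosen only after the result was seen are those of the interferon-stimulated list and of the M1 list against single libraries and the length and GC trend, and that of the library totals. Among the split comparisons of single lists, only that of the ribosomal protein list had a criterion set in advance. DDO, FCRLA, FCRLB, SARAF, OTUD1, SNX10, CREM, PDE4A, PDE4B, DCSTAMP and OCSTAMP lie outside the rule for named genes and were chosen after their values were seen.

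Besides ROR2, several genes of low p had non-overlapping groups without passing the edgeR threshold in the filtered fit without offsets, and were called with length and GC offsets and with DESeq2. DDO, a D-aspartate oxidase, had 7.13 ± 0.57 CPM with control siRNA and 1.64 ± 0.46 CPM with circ siRNA. Without the filter, edgeR called DDO as well as ROR2. FCRLA and its chromosome 1 neighbour FCRLB, Fc receptor-like genes, had 117 ± 12.0 and 49.5 ± 8.01 CPM, and 7.93 ± 1.67 and 3.60 ± 0.99 CPM; FCRLB was called with DESeq2 and not with the offsets. SARAF, a regulator of store-operated calcium entry, had 145 ± 11.5 and 80.0 ± 7.42 CPM. Higher values were found for OTUD1, a deubiquitinase, with 136 ± 6.68 and 237 ± 17.5 CPM, and for SNX10, a sorting nexin, with 23.2 ± 1.40 and 41.6 ± 3.43 CPM. Among named list members with non-overlapping groups, MMP19 had a log2 fold change of 0.55 and the matrix genes TIMP3 and MMP7 had -0.62 and -0.78, TREM1 and CLEC4E, receptors of myeloid cells, had 0.78 and 0.98, and CHI3L1 had -0.33, none of them past the edgeR threshold; of these 6, DESeq2 called TREM1, CLEC4E and TIMP3 (adjusted p = 0.00857, 0.0240 and 0.0468).

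Control library 1 and circ library 3 lay apart from the other 4 libraries. Their totals, 16588112 and 14793902 counts, lay on either side of the mean of the other 4 and 92.3% of the range of all 6 totals apart, which argues against a shared depth; thinning every library to the smallest total left 100.6% of the squared difference but removed at most 11.6% of the counts of any library, so it decided nothing. Removing each library's length and GC trend left 69.1%, so a bias of that kind may account for a part, and the rest stays open. Because the pair holds 1 library of each group, no biological explanation from the design was tested. Among the 10 splits of the 6 libraries, the real one called 1 gene and the highest other 1636, in the split that put control library 1 with circ libraries 1 and 3, which also parts the libraries by the sign of the first component and points to a structure of the samples; the remaining 8 splits called 0 genes, among them the other 3 that kept control library 1 and circ library 3 together, so 2 splits, the real one included, called at least 1. For lists the real split called 6 and the highest other 15, with 6 splits, the real one included, at or above the real count. With 10 splits no share under 0.05 can be reached.

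The interferon-stimulated list was higher in every circ library than in every control library. After length and GC offsets its median was 0.146 (camera adjusted p = 7.56e-05, adjusted p = 0.459 with an estimated correlation), and without control library 1 and circ library 3 its mean was 0.2002 (camera adjusted p = 0.000103, adjusted p = 0.736 with an estimated correlation), which argues against the trend and against those libraries as the whole cause. In the real split its mean was 0.18, and the highest of the other splits gave 0.09. The M1 list (0.38 against 0.28) and the immediate early list (0.25 against 0.18) also had their highest mean in the real split. The inflammasome list did not (0.192 against 0.198). These lists were compared because they were called in the real split, so a high mean there is no independent support. With 10 splits the exact permutation p cannot go below 0.1. The call of the interferon-stimulated list rests on the preset correlation. An innate response to 1 siRNA sequence rather than to loss of its target stays open, since 1 siRNA label per group cannot separate them. A biological effect of the knockdown is a hypothesis that these data leave untested.

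Without circ library 3 the M1 list mean was 0.207, between the bounds set for and against that library as the cause, so its part stays open. For the ribosomal protein list, 5 of the 10 splits gave a mean as far from 0 as the real -0.25, with 0.598 as the highest other, and for the oxidative phosphorylation list 4 of the 10 were as far from 0 as the real -0.21, with 0.469 as the highest other.

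Further hypotheses were tested with criteria set before their results were seen. The first wording of 3 criteria, that any p of 0.05 or more, or any equal score in another split, would count against a hypothesis, was replaced before the tests were run by a bound on the size of the value; by the first wording, the cAMP and seed hypotheses would have been counted against. CREM, PDE4A, PDE4B and FOSB, targets or regulators of cAMP signalling, had log2 fold changes of 0.97, 0.67, 0.94 and 1.06, none past the edgeR threshold with or without offsets and all 4 called with DESeq2, and a candidate explanation is a cAMP-responsive programme. In 13 other cAMP targets the mean was 0.144 (SE over genes 0.09), with 10 positive and 3 negative values. Camera in limma gave an unadjusted p of 0.0812 for this list, which neither meets the criterion nor excludes the explanation. DCSTAMP and OCSTAMP, needed for macrophage fusion, had log2 fold changes of -0.75 and -1.11, not past the edgeR threshold without offsets; OCSTAMP was called with the offsets (edgeR adjusted p = 0.0351) and both with DESeq2 (adjusted p = 0.0116 and 7.40e-08). However, 14 other genes of cell fusion and osteoclasts had a mean of 0.071 (SE over genes 0.04), with 8 positive and 6 negative values. They were thus not lower as a list, which met the bound set against a lower fusion programme. The SE over genes leaves out the spread between libraries, and camera gave an unadjusted p of 0.224, so these values do not exclude such a programme. A shared seed match of the siRNA was sought as a 7-base word in 3' UTRs that marks lower genes, over 12320 genes. The best word scored 4.77, against 6.43 for the highest and 4.44 for the median of the other 9 splits. In those splits the score was the larger for words marking lower or higher genes, and 6.43 belonged to a word marking higher genes. Among words marking lower genes only, the most extreme score was -5.71 in those splits and -4.77 in the real split. An off-target effect could therefore be neither shown nor excluded.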
